A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

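Messenger RNA was compared between yeast (Saccharomyces cerevisiae, strain S288C, a laboratory strain) recovering from a freeze and the same kind of culture before it was frozen. Per the labels, cells were grown in rich medium at 30 °C to an absorbance of 1.0, and an aliquot of 400 ml was kept at -80 °C for 1 week with no cryoprotectant. It was thawed for 25 min in a water bath at 30 °C, incubated further, and sampled 15, 30 or 60 min after thawing was complete. The control was an aliquot of 200 ml taken before freezing. The culture volume was 600 ml and the volume sampled during recovery 100 ml. Poly(A) RNA was copied from an oligo(dT) primer with Cy5 for the recovering cells (channel 1) and Cy3 for the control (channel 2), and the dyes were not exchanged on any array. Each of the 3 time points had 3 arrays, which the series describes as independent biological samples.

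The deposited values are log2 ratios to which the authors applied LOWESS normalization, an intensity-dependent correction within each array, using the spots with flag value 0. The lowest deposited value equals the log2 of 0.01, which set the log base. The scanner, image software, background correction and the meaning of the flag values are not given in the sources used here, and the tables used here hold no channel intensities, background levels or flags. The direction of the ratio is not stated in the tables. It was read as recovering over before freezing because the labels name each array for the recovering sample and put it in channel 1. All 36 correlations between pairs of arrays, taken across genes, were positive (0.09 to 0.70), so the arrays share 1 direction, and every sign given would turn if the ratio had been formed the other way. The number of arrays, 3 per time point, limits the precision of each mean.

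Replicate 1 of each time point was on a first array platform and replicates 2 and 3 on a second, each with 6272 spots. A gene symbol was given for 5297 spots of the first and 5291 of the second platform, and spots of 1 gene were averaged. The 5189 genes on both platforms were used, of which 5185 matched the RefSeq annotation of assembly R64, used here for names only. Chromosomal positions are not given because the tables used here name no genome build. Of the 86 genes with more than 1 spot, 1 (APE2) had spots that differed by over 1 log2 unit (median difference 1.64). The median difference over the 86 genes was 0, so many of these spots held the same value. They cannot show how well separate spots agree. The 961 spots without a symbol on both platforms were left out of the comparisons, except where every spot was tested on its own. Missing values were not filled in.

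All 9 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per time point and no term for platform or replicate number. Each time point was tested against a log2 ratio of 0 and each pair of time points against each other, two-sided, with moderated statistics and Benjamini-Hochberg adjustment. A gene was tested when all 3 arrays of each time point compared had a value, and passed at an adjusted p under 0.05. Errors are standard errors from limma, or the SD of the 3 arrays where marked. Each gene had 1 moderated spread for all times, so its standard error was the same at each time tested. It does not show the spread of the 3 arrays at 1 time. The labels do not say whether arrays shared a control culture, and where they did, testing the ratio against 0 leaves out the spread between control cultures.

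A total of 39 gene lists, written before the data were examined, covered chaperones, proteolysis, stress defence, translation, energy metabolism, biosynthesis, transport, the cell wall and cytoskeleton, chromatin, the cell cycle, mating type, sporulation and the mitochondrial genome. Lists with at least 5 tested members were compared with all other tested genes by the camera formula of limma, applied to the moderated statistics with a preset correlation of 0.01 between genes. It was repeated with the correlation estimated from the residuals of the members with 9 values (6 degrees of freedom), which ended the call of every list at every time point and contrast. Counts of members that passed are given over all genes tested and adjusted over the list alone. The list of mitochondrial genome transcripts (8 genes) had 0 members on the arrays and was not tested. Lists were adjusted together within each comparison.

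The genes named were chosen by a rule fixed before the data were examined. For each time point these were the 10 passed genes with the largest mean ratio in each direction that had a standard name and 1 sign on all 3 arrays, and up to 4 passed members of each list that was called, in the direction of the list. For each pair of time points they were the 5 passed genes with the largest difference in each direction, and where fewer than 5 passed, the 5 smallest unadjusted p in that direction as values that did not pass. The results of 1 gene that the rule chose are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

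The procedure was tested on simulated data in which 200 genes were shifted. The noise was independent and normal, with each gene's moderated SD and the real missing values. It held no correlation between genes or between arrays, so the shares recovered may differ from those in the real data. A shift of 1 log2 unit was recovered in 57.0% of genes at 15 min, 60.0% at 30 min and 61.5% at 60 min, and in 9.5% for the difference between 60 and 15 min. A shift of 2 log2 units was recovered in 100% of genes at each time point and in 98.5% for that difference. In 100 simulated sets of unchanged arrays that shared control channels, 0 genes were called at all 3 times or at any pair of times by limma. Because these sets held no changed genes, they cannot show how much agreement shared controls would add where many genes are called.

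Alternatives named before the data were examined were centring each array on its median, setting all arrays to 1 median absolute deviation, a replicate block, array weights, robust moderation, a spread from the time points compared alone, values on at least 2 of 3 arrays, every spot on its own, leaving out genes with an absolute ratio over 5, a minimum absolute change of 1 log2 unit, leaving out each array, camera with an estimated correlation, the rotation test fry, and leaving out ribosomal protein genes with an A and a B copy. An A and a B copy counted as a pair only where both genes were on the arrays. Alternatives added after seeing the data were a platform block, the second platform alone, and setting to missing the values that ribosomal protein and glycolysis genes share within an array. Centring shifted the 60 min replicate 2 array by the most, its median over genes being -0.18, and the other medians lay between -0.04 and 0.05.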

Results

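The data were 9 two-channel arrays of yeast mRNA, each comparing cells 15, 30 or 60 min after thawing with cells before freezing. Of the 6272 spots per array, 2765, 3441 and 5772 had a value on the 3 arrays at 15 min. The numbers were 5038, 4208 and 5225 at 30 min and 3877, 4436 and 5209 at 60 min. The SD of the log2 ratios of an array was 0.634, 0.798 and 0.440 at 15 min, 0.733, 0.618 and 0.555 at 30 min, and 1.02, 0.980 and 0.674 at 60 min. Across genes, which are not independent replicates, arrays of 1 time point correlated at 0.15 to 0.30 at 15 min, 0.35 to 0.56 at 30 min and 0.60 to 0.66 at 60 min. Each time point was first compared with the culture before freezing, to show which transcripts differed during recovery. Ratios are taken as recovering over before freezing, which the labels make likely and the tables do not state, and each sign would turn in the other case.

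At 15 min after thawing, 18 genes were higher and 7 lower than before freezing, of 2148 tested in limma, and 375 had an unadjusted p under 0.05. The gene with the largest rise was MSC1 (YML128C), a stress-responsive gene, at 2.40 ± 0.37 (log2 mean ± SE, n = 3; 5.27-fold, adjusted p = 0.000299). ARO9 (YHR137W), an aromatic aminotransferase, rose 4.98-fold (2.32 ± 0.30, n = 3, adjusted p = 2.98e-05). HSP104 (YLL026W), a disaggregase that rescues aggregated proteins, rose 4.67-fold (2.22 ± 0.29, n = 3, adjusted p = 2.98e-05). The gene with the largest fall, ARO5 (YGL117W), was 2.66-fold lower (-1.41 ± 0.28, n = 3, adjusted p = 0.00771), and DED1, an RNA helicase of translation initiation, was 2.60-fold lower (-1.38 ± 0.33, n = 3, adjusted p = 0.0311).

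The lists of chaperones and general stress genes were called as higher at 15 min. Of 29 measured heat shock proteins and chaperones, 5 passed and were higher over all genes, 10 adjusted over the list alone, and 0 were lower (median 0.45, adjusted p = 6.91e-09, and adjusted p = 0.234 with an estimated correlation). Beside HSP104 they included HSP12 (1.90 ± 0.34), a membrane-associated small heat shock protein, SSA4 (1.74 ± 0.30), a stress-induced Hsp70, and BTN2 (1.47 ± 0.32), which sorts misfolded proteins. Of 9 general stress genes of the Msn2/4 type, 5 were higher over all genes and 6 adjusted over the list alone (median 1.51, adjusted p = 7.53e-10, and adjusted p = 0.234 with an estimated correlation). They included OM45 (1.80 ± 0.33), a mitochondrial outer membrane protein, SPI1 (1.64 ± 0.33), a cell wall protein, and YGP1 (1.54 ± 0.30), a secreted glycoprotein. CYC7, an isoform of cytochrome c, was at 1.64 ± 0.34 and RTC3 at 1.87 ± 0.45 (adjusted p = 0.0107 and 0.0327).

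Lists of reserve carbohydrate, carbon and iron metabolism and oxidative stress were also called as higher at 15 min. In trehalose and glycogen metabolism 1 of 8 genes passed (3 adjusted over the list alone, median 0.73, adjusted p = 0.00109, and adjusted p = 0.348 with an estimated correlation), namely PGM2, a phosphoglucomutase, at 1.54 ± 0.38. In gluconeogenesis, glyoxylate and acetate use 1 of 7 passed (3 adjusted over the list alone, median 0.58, adjusted p = 0.00245, and adjusted p = 0.278 with an estimated correlation), namely ALD4, an aldehyde dehydrogenase, at 1.48 ± 0.38. Of 13 iron and copper genes 1 passed (3 adjusted over the list alone, median 0.40, adjusted p = 0.00876, and adjusted p = 0.234 with an estimated correlation), namely SIT1, a siderophore transporter, at 1.47 ± 0.31. The oxidative stress list (26 genes, median 0.40, adjusted p = 0.000714, and adjusted p = 0.311 with an estimated correlation) had 0 genes that passed in limma, 10 at an unadjusted p under 0.05 and 7 adjusted over the list alone. Glycolysis and alcohol fermentation (22 genes, median 0.27, adjusted p = 0.0145, and adjusted p = 0.549 with an estimated correlation) had 0 genes passed in limma, 3 at an unadjusted p under 0.05 and 2 adjusted over the list alone. The TCA cycle list (11 genes, median 0.43, adjusted p = 0.0334, and adjusted p = 0.410 with an estimated correlation) had 0 genes passed in limma, 2 at an unadjusted p under 0.05 and 1 adjusted over the list alone.

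Lists of ribosome production were called as lower at 15 min. In ribosome biogenesis 1 of 66 genes passed and 11 adjusted over the list alone, all lower (median -0.51, adjusted p = 7.53e-10, and adjusted p = 0.343 with an estimated correlation). That gene was DRS1, a helicase of ribosome assembly, at -1.27 ± 0.31. Of 117 cytosolic ribosomal protein genes 1 passed and 14 adjusted over the list alone, all lower (median -0.34, adjusted p = 2.53e-07, and adjusted p = 0.311 with an estimated correlation). That gene was RPS6A, at -1.25 ± 0.29. RNA polymerase I and III (16 genes, median -0.48, adjusted p = 0.00109, and adjusted p = 0.344 with an estimated correlation) had 0 genes passed in limma, 6 at an unadjusted p under 0.05 and 1 adjusted over the list alone. In purine and pyrimidine synthesis 1 of 19 genes was lower over all genes, and 5 were lower and 1 higher adjusted over the list alone (median -0.30, adjusted p = 0.0334, and adjusted p = 0.348 with an estimated correlation). It was FUR1, a uracil salvage enzyme, at -1.26 ± 0.29. SAS10, of the small-subunit processome, was at -1.20 ± 0.31 and YHB1, a flavohemoglobin, at -1.19 ± 0.29 (adjusted p = 0.0467 and 0.0341).

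Lists not called at 15 min with 1 gene higher were vacuole, autophagy and proteases (of 14), amino acid biosynthesis (of 44), cell wall (of 30) and the respiratory chain (of 26), and translation factors had 1 gene lower (of 32). The other 17 lists not called had 0 genes passed in limma among 251 memberships and 30 at an unadjusted p under 0.05. Without replicate 1, 2 or 3 the count of higher genes at 15 min was 11, 5 and 5, and that of lower genes 1, 0 and 3. Setting all arrays to 1 median absolute deviation gave 44 higher and 18 lower, and centring each array on its median 12 and 2. MSC1, ARO9 and HSP104 passed without any 1 of the arrays, 18 other named genes did not, and the call of the glycolysis list ended without replicate 1 (median 0.18, adjusted p = 0.0598) or 2 (0.18, 0.0884). That of the TCA list ended without replicate 1 (0.31, 0.0770) or 3 (0.20, 0.253), and that of the purine and pyrimidine list without replicate 1 (-0.44, 0.0891) or 3 (-0.28, 0.102). DED1 was at -0.64, -2.64 and -0.86 on the 3 arrays, and without replicate 2 its mean was -0.75 (adjusted p = 0.460).

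At 30 min, 76 genes were higher and 68 lower than before freezing, of 3320 tested in limma, and 609 had an unadjusted p under 0.05. HSP12 (YFL014W) was 8.19-fold higher (3.03 ± 0.34, n = 3, adjusted p = 2.77e-06), MSC1 6.69-fold (2.74 ± 0.37, n = 3, adjusted p = 2.40e-05) and SSA4 (YER103W) 5.79-fold (2.53 ± 0.30, n = 3, adjusted p = 4.59e-06). FIT2 (YOR382W), a cell wall mannoprotein that retains siderophore iron, rose 5.53-fold (2.47 ± 0.29, n = 3, adjusted p = 7.55e-06). The largest falls were those of SGD1 (YLR336C, -1.91 ± 0.36, 3.75-fold, adjusted p = 0.00230), SPB1 (YCL054W), an rRNA methyltransferase (-1.62 ± 0.33, 3.07-fold, adjusted p = 0.00342), and RTP1 (YMR185W, -1.57 ± 0.28, 2.98-fold, adjusted p = 0.000742), each with n = 3.

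Ribosome biogenesis was the list with the most genes lower at 30 min. Of 78 measured members 21 were lower over all genes, 54 adjusted over the list alone, and 0 were higher (median -0.81, adjusted p = 2.60e-24, and adjusted p = 0.126 with an estimated correlation). DBP3, a ribosome assembly helicase, was at -1.49 ± 0.30, and the large-subunit assembly factors MAK21 and NOC2 were at -1.30 ± 0.30 and -1.26 ± 0.28. Of 109 cytosolic ribosomal protein genes 4 were lower, 6 adjusted over the list alone, and 0 higher (median -0.39, adjusted p = 8.80e-07, and adjusted p = 0.30 with an estimated correlation). They were RPL6B (-1.17 ± 0.31), RPL17A (-1.06 ± 0.28), RPS7A (-1.06 ± 0.29) and RPL27B (-1.02 ± 0.28). In RNA polymerase I and III 1 of 18 genes was lower and 3 adjusted over the list alone (median -0.52, adjusted p = 0.000166, and adjusted p = 0.305 with an estimated correlation), namely RPO31, the largest subunit of polymerase III, at -1.02 ± 0.29. In purine and pyrimidine synthesis 1 of 25 genes was lower, and 6 were lower and 1 higher adjusted over the list alone (median -0.46, adjusted p = 0.0274, and adjusted p = 0.320 with an estimated correlation), namely URA1 at -1.001 ± 0.29. In amino acid biosynthesis 1 of 52 genes was lower and 1 higher, the same numbers adjusted over the list alone (median -0.29, adjusted p = 0.0357, and adjusted p = 0.487 with an estimated correlation), the lower one being LYS4 at -1.08 ± 0.29. Other named genes that were lower were LSM2 (-1.44 ± 0.36), ARO5 (-1.43 ± 0.28), PXR1 (-1.41 ± 0.29), HCA4 (-1.39 ± 0.29), KAP123, an importin (-1.38 ± 0.35), and TIF11, initiation factor eIF1A (-1.37 ± 0.28).

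The chaperone, general stress and oxidative stress lists were called as higher at 30 min. Of 32 heat shock proteins and chaperones 6 were higher, 12 adjusted over the list alone, and 0 lower (median 0.47, adjusted p = 1.65e-10, and adjusted p = 0.126 with an estimated correlation). HSP26, a small heat shock protein, was at 2.21 ± 0.32 and BTN2 at 2.17 ± 0.32. Of 15 general stress genes 7 were higher, 8 adjusted over the list alone, and 0 lower (median 0.87, adjusted p = 3.43e-09, and adjusted p = 0.30 with an estimated correlation), with SPI1 at 2.35 ± 0.33, the cytosolic catalase CTT1 at 2.18 ± 0.39 and TFS1 at 1.94 ± 0.38. Of 31 oxidative stress genes 5 were higher, 9 adjusted over the list alone, and 0 lower (median 0.53, adjusted p = 1.59e-08, and adjusted p = 0.126 with an estimated correlation), with GRE2 at 1.67 ± 0.32, the thiol peroxidase AHP1 at 1.56 ± 0.29 and the mitochondrial peroxiredoxin PRX1 at 1.40 ± 0.30. RTC3 (2.43 ± 0.45), FMP16 (2.41 ± 0.36), ARO9 (2.40 ± 0.30) and HBT1 (2.20 ± 0.36) were also among the 10 largest rises.

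Proteolysis, reserve carbohydrate and iron lists were higher at 30 min as well. The 26S proteasome list (33 genes, median 0.48, adjusted p = 4.03e-06, and adjusted p = 0.320 with an estimated correlation) had 0 genes passed in limma, 8 at an unadjusted p under 0.05 and 5 adjusted over the list alone. Of 19 ubiquitin and Cdc48 genes 1 was higher and 2 adjusted over the list alone (median 0.49, adjusted p = 6.19e-06, and adjusted p = 0.126 with an estimated correlation), namely the polyubiquitin gene UBI4 at 1.36 ± 0.28. Of 15 trehalose and glycogen genes 6 were higher, 7 adjusted over the list alone, and 0 lower (median 0.64, adjusted p = 1.57e-05, and adjusted p = 0.320 with an estimated correlation). PGM2 was at 2.19 ± 0.38, the trehalose synthase subunits TSL1 and TPS2 at 2.07 ± 0.31 and 1.60 ± 0.33, and the glycogen phosphorylase GPH1 at 1.503 ± 0.32. Of 17 iron and copper genes 3 were higher, 4 adjusted over the list alone, and 0 lower (median 0.42, adjusted p = 5.74e-05, and adjusted p = 0.114 with an estimated correlation). They were the siderophore transporters SIT1 (1.79 ± 0.31) and ENB1 (1.62 ± 0.31) and the ferroxidase FET3 (1.74 ± 0.30).

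Smaller shifts at 30 min were called for lists of carbon metabolism, the vacuole and actin. Of 19 TCA cycle genes 3 were higher and 5 adjusted over the list alone (median 0.16, adjusted p = 0.00475, and adjusted p = 0.353 with an estimated correlation), namely the isocitrate dehydrogenase subunits IDH1 (1.45 ± 0.32) and IDH2 (1.37 ± 0.32) and the pyruvate carboxylase PYC1 (1.07 ± 0.31). In glycolysis and alcohol fermentation 1 of 19 genes was higher, also adjusted over the list alone (median 0.41, adjusted p = 0.0274, and adjusted p = 0.566 with an estimated correlation), namely the glucokinase GLK1 at 1.68 ± 0.36. Of 19 vacuole, autophagy and protease genes 2 were higher, and 3 were higher and 1 lower adjusted over the list alone (median 0.04, adjusted p = 0.0447, and adjusted p = 0.320 with an estimated correlation), namely APE3 (1.43 ± 0.29) and the autophagy receptor ATG19 (0.96 ± 0.28). The actin list (27 genes, median 0.27, adjusted p = 0.0273, and adjusted p = 0.353 with an estimated correlation) had 0 genes passed in limma, 8 at an unadjusted p under 0.05 and 0 adjusted over the list alone.

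Among lists not called at 30 min, cell wall had 4 genes higher and 1 lower of 35 and translation factors 2 lower of 33. The respiratory chain had 2 higher of 26, cell cycle regulators 1 lower of 25, and 1 gene was higher in each of protein folding in the endoplasmic reticulum (of 15), glycerol and osmotic stress (of 14), sulfur and methionine (of 16) and DNA repair (of 7). The other 14 lists not called had 0 genes passed in limma among 226 memberships and 18 at an unadjusted p under 0.05. Without replicate 1, 2 or 3 the count of higher genes at 30 min was 22, 11 and 58, and that of lower genes 5, 3 and 26. The second platform alone (replicates 2 and 3) gave 29 higher and 5 lower, setting all arrays to 1 median absolute deviation 159 and 169, and array weights 244 and 412. Of the 49 named genes HSP12, MSC1, SSA4, FIT2, FMP16, ARO9, SPI1, RTP1 and BTN2 passed without any 1 array. LSM2 was at -2.85, -1.27 and -0.19, and its mean was -0.73 without replicate 1 (adjusted p = 0.479), while that of URA1 was -0.66 without replicate 3 (0.451). Without replicate 1 the call of the TCA list ended and its median turned from 0.16 to -0.0549 (adjusted p = 0.0946). The calls of the glycolysis (0.22, 0.0941), purine and pyrimidine (-0.27, 0.123), amino acid (-0.30, 0.115) and vacuole (0.0686, 0.182) lists ended there as well. Without replicate 2 those of glycolysis (0.0827, 0.0835) and actin (0.31, 0.0755) ended. Without replicate 3 those of actin (0.33, 0.0755), purine and pyrimidine (-0.31, 0.0983), amino acid (-0.27, 0.142) and vacuole (0.00392, 0.0868) ended.

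At 60 min, 461 genes were higher and 518 lower than before freezing, of 2952 tested in limma, and 1289 had an unadjusted p under 0.05. By at least 2-fold, 293 of them were higher and 278 lower. YGP1 (YNL160W) rose 18.1-fold (4.18 ± 0.30, n = 3, adjusted p = 1.71e-10), HSP12 16.3-fold (4.03 ± 0.34, n = 3, adjusted p = 1.34e-09) and HSP26 (YBR072W) 15.9-fold (3.99 ± 0.32, n = 3, adjusted p = 6.64e-10). ARO5 was 8.29-fold lower (-3.05 ± 0.28, n = 3, adjusted p = 9.26e-09), and IZH4 (YOL101C), a membrane protein, 6.01-fold lower (-2.59 ± 0.30, n = 3, adjusted p = 8.20e-07). PUS7, a pseudouridine synthase, had the lowest mean (-3.10 ± 0.56, n = 3), with replicate 1 at the lowest value deposited, -6.64, and replicates 2 and 3 at -1.69 and -0.96.

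**Figure D1:**
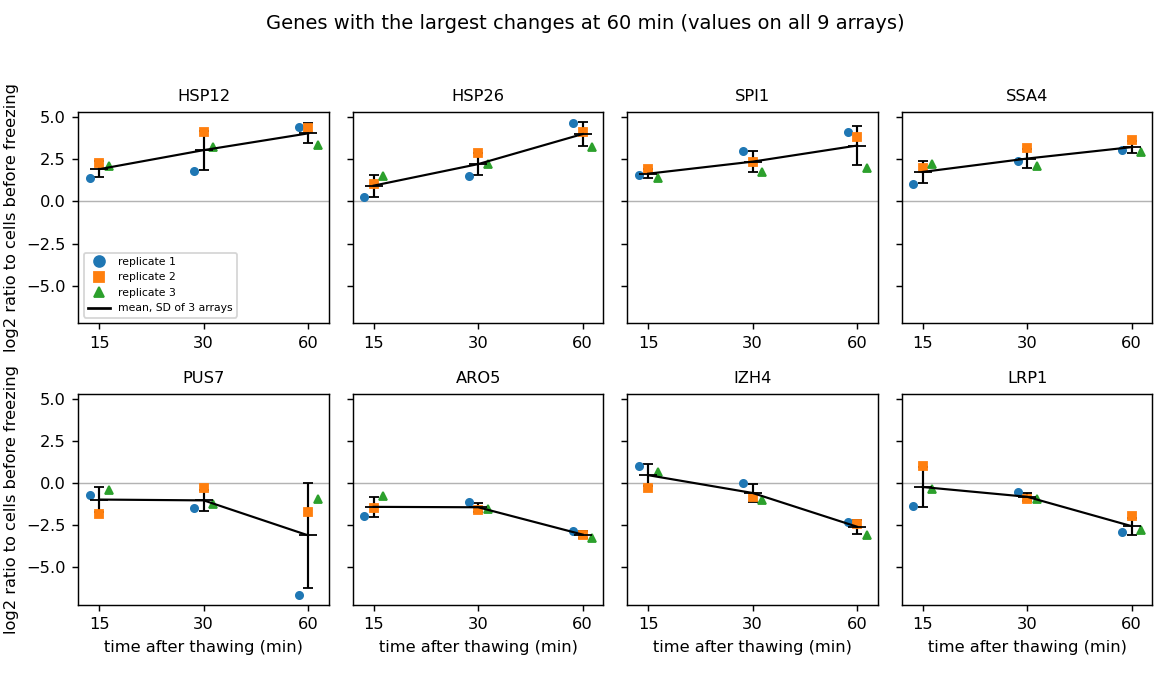
Log2 ratio to cells before freezing (vertical axis) at 15, 30 and 60 min after thawing (horizontal axis, times evenly spaced) for the genes with values on all 9 arrays that had the largest rises (top) and falls (bottom) at 60 min. Points are arrays and lines with bars are the mean and SD of 3 arrays: HSP12 went from a mean of 1.90 to 3.03 and 4.03, and the low mean of PUS7 at 60 min rests on replicate 1 at -6.64.

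Lists of stress defence were called as higher at 60 min, each with at least 1 member lower. Of 14 general stress genes 11 were higher and 1 lower, and adjusted over the list alone 11 and 2 (median 1.76, adjusted p = 8.35e-07, and adjusted p = 0.437 with an estimated correlation). SPI1 was at 3.31 ± 0.33, MSC1 at 2.47 ± 0.37 and CTT1 at 2.40 ± 0.39. On replicates 1, 2 and 3 at 60 min MSC1 was at 3.66, 2.87 and 0.88, and CTT1 at 3.59, 2.61 and 0.99. The member that was lower was the transcription factor gene MSN4, at -0.98 ± 0.32, a gene chosen after its values were seen. Of 30 heat shock proteins and chaperones 15 were higher and 4 lower, and adjusted over the list alone 16 and 5 (median 0.80, adjusted p = 5.01e-05, and adjusted p = 0.437 with an estimated correlation), with SSA4 at 3.21 ± 0.30 and HSP31 at 2.31 ± 0.34. Of 33 oxidative stress genes 19 were higher and 2 lower, the same numbers adjusted over the list alone (median 0.97, adjusted p = 8.35e-07, and adjusted p = 0.329 with an estimated correlation). The glutaredoxin GRX1 was at 2.20 ± 0.32, the thioredoxin TRX1 at 2.14 ± 0.31 and PRX1 at 2.06 ± 0.30.

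The TCA cycle, iron and reserve carbohydrate lists were called as higher at 60 min, each with 1 member lower. Of 17 TCA cycle genes 8 were higher and 1 lower, and adjusted over the list alone 9 and 1 (median 0.79, adjusted p = 0.000177, and adjusted p = 0.437 with an estimated correlation). Over the 10 members with values on all 9 arrays, the medians of replicates 1, 2 and 3 at 60 min were 1.57, -0.05 and 0.39. IDH1 was at 2.46 ± 0.32, IDH2 at 2.28 ± 0.32, the malate dehydrogenase MDH1 at 1.91 ± 0.31 and the succinate dehydrogenase subunit SDH2 at 1.64 ± 0.32. COX5B, a cytochrome c oxidase subunit made mostly at low oxygen, was at 2.65 ± 0.31. Of 17 iron and copper genes 9 were higher and 1 lower, and adjusted over the list alone 11 and 1 (median 0.81, adjusted p = 0.00770, and adjusted p = 0.329 with an estimated correlation), among them FET3 (1.53 ± 0.30), the siderophore transporter ARN2 (1.45 ± 0.30), the copper transporter CTR1 (1.43 ± 0.35) and the iron-sulfur scaffold ISU1 (1.40 ± 0.31). Of 9 trehalose and glycogen genes 5 were higher and 1 lower, and adjusted over the list alone 6 and 1 (median 0.93, adjusted p = 0.0137, and adjusted p = 0.646 with an estimated correlation). PGM2 was at 2.88 ± 0.38, the glycogen synthase GSY2 at 1.86 ± 0.33, GPH1 at 1.44 ± 0.32 and UGP1 at 0.93 ± 0.30.

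Lists of ribosome assembly, RNA polymerases and histones were called as lower at 60 min. Of 81 ribosome biogenesis genes 55 were lower over all genes and 0 higher, and adjusted over the list alone 58 were lower and 1 higher (median -1.01, adjusted p = 1.43e-15, and adjusted p = 0.437 with an estimated correlation). KRR1, of the small subunit, was at -2.40 ± 0.31, DBP3 at -2.33 ± 0.30, NOC2 at -2.14 ± 0.28 and NHP2, a protein of the H/ACA particles, at -1.93 ± 0.36. Also among the largest falls were LRP1, an exosome cofactor (-2.55 ± 0.33), RSA3 (-2.48 ± 0.31), DIA1 (-2.32 ± 0.33), IZH2 (-2.31 ± 0.33) and BCP1 (-2.23 ± 0.30). Of 17 RNA polymerase I and III genes 6 were lower and 0 higher, 10 lower adjusted over the list alone (median -0.67, adjusted p = 0.00369, and adjusted p = 0.596 with an estimated correlation). They included RPA190 (-1.43 ± 0.30), RPC19 (-1.43 ± 0.28), RPA43 (-1.17 ± 0.31) and RPC53 (-0.97 ± 0.29). Of 8 core histone genes 5 were lower and 0 higher, 6 lower adjusted over the list alone (median -0.96, adjusted p = 0.0192, and adjusted p = 0.646 with an estimated correlation). HHT2 was at -1.56 ± 0.30, HTA1 at -1.496 ± 0.32, HTB2 at -1.39 ± 0.30 and HHF1 at -1.19 ± 0.31.

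The list of cytosolic ribosomal proteins was not called at 60 min (115 genes, median -0.21, adjusted p = 0.512), with 8 genes higher and 10 lower, and 5 and 6 adjusted over the list alone. On 5 of the 9 arrays, ribosomal protein and glycolysis genes gathered at 1 value within 0.01 log2 units. That value was 0.47 on replicate 1 at 15 min (11 of 140 genes of both lists), 0.003 on replicate 3 at 15 min (26 of 144) and 0.19 on replicate 3 at 30 min (26 of 131). It was 0.13 on replicate 2 at 60 min (17 of 141) and -0.30 on replicate 3 at 60 min (15 of 143). Setting these values to missing left the ribosomal protein list called at 15 min (median -0.39) and 30 min (median -0.50). It ended the calls of the glycolysis list at 30 min (median 0.06, adjusted p = 0.149) and of the core histones between 15 and 60 min (-0.41, adjusted p = 0.151), and left too few histone genes to test between 30 and 60 min. Of the genes outside both lists, 0.78% to 2.33% lay within the same windows on these 5 arrays. Lying there thus does not by itself mark a gene as affected.

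**Figure D2:**
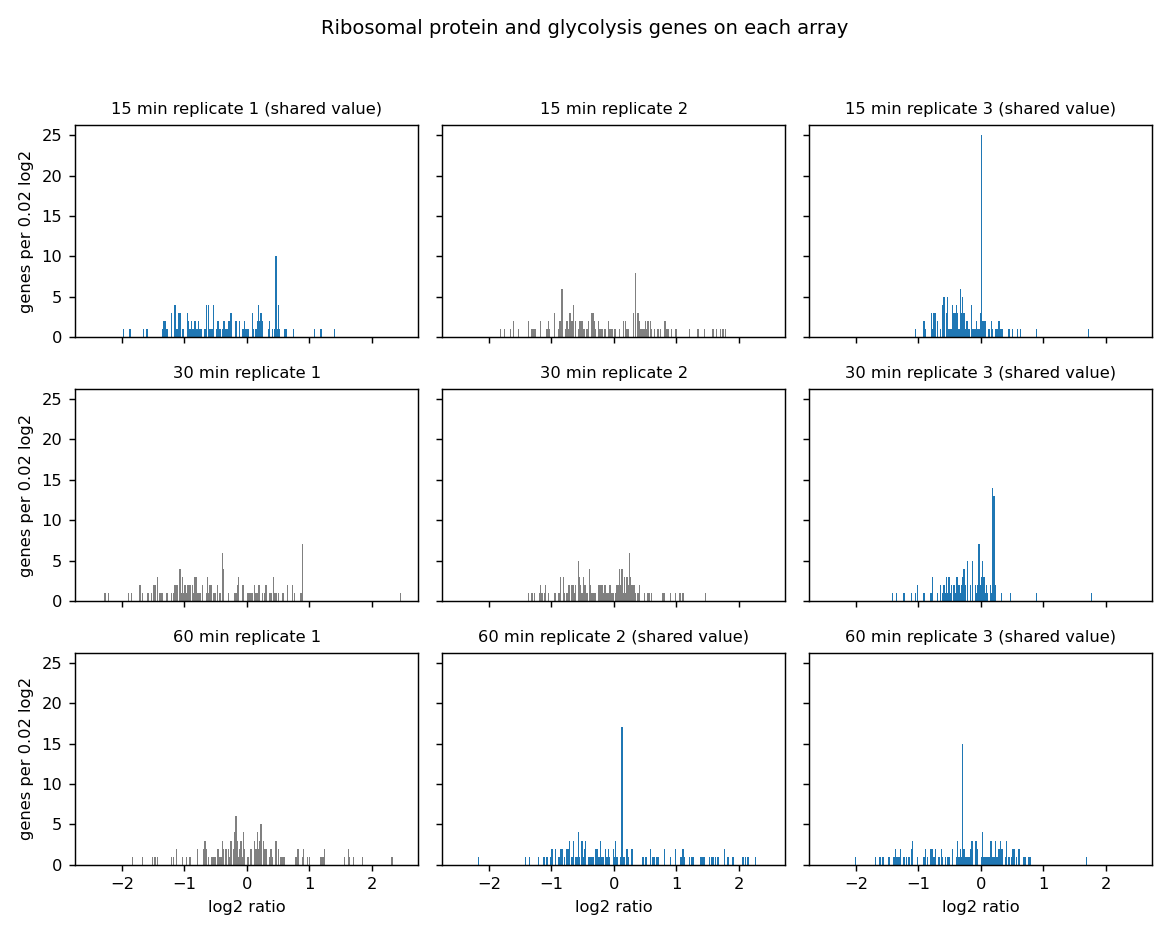
Histograms of the log2 ratios (horizontal axis) of ribosomal protein and glycolysis genes on each of the 9 arrays, as genes per 0.02 log2 units (vertical axis). On the 5 arrays drawn in blue many genes fall at 1 value, such as 26 of 144 within 0.01 of 0.003 on replicate 3 at 15 min.

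Other lists at 60 min were not called, and most had members that passed in both directions. The 26S proteasome had 13 genes higher and 2 lower of 36, the respiratory chain 10 and 1 of 29, cell wall 11 and 4 of 35, glycolysis and alcohol fermentation 8 and 3 of 24, and actin 7 and 2 of 22. Vacuole, autophagy and proteases had 7 higher and 2 lower of 19, mitochondrial ribosomal proteins 6 and 4 of 54, amino acid biosynthesis 3 and 14 of 45, translation factors 1 and 9 of 32, and fatty acid, sphingolipid and phospholipid synthesis 2 and 6 of 20. Purine and pyrimidine synthesis had 2 higher and 5 lower of 25, ergosterol biosynthesis 3 and 3 of 18, sulfur and methionine 4 and 3 of 16, ubiquitin and Cdc48 3 and 2 of 16, and cell cycle regulators 4 and 1 of 16. Phosphate starvation had 3 and 1 of 17, multidrug transporters 2 and 2 of 13, the chaperonin CCT and prefoldin 1 and 2 of 11, glycerol and osmotic stress 2 and 1 of 10, and mating type and pheromone 1 and 1 of 5. Protein folding in the endoplasmic reticulum had 2 higher of 13 and hexose transport 2 higher of 7. Nitrogen catabolite genes had 3 lower of 17, gluconeogenesis 2 lower of 9, cold-induced and anaerobic mannoprotein genes 2 lower of 7, and DNA repair 1 lower of 7. Beta-oxidation and peroxisome genes had 0 of 8 passed in limma and 2 at an unadjusted p under 0.05. The meiosis and sporulation list had too few tested members at 60 min and was not called at 30 min (8 genes, median -0.08, adjusted p = 0.951).

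Median, mean and test differed in sign for some lists, none of them called. At 60 min, gluconeogenesis had a median of 0.19 and a mean of -0.10, ergosterol biosynthesis -0.06 and 0.03, sulfur and methionine -0.09 and 0.04, and multidrug transporters -0.32 and 0.01. Mating type and pheromone genes had a median of -0.05 and a mean of 0.40, and DNA repair 0.05 and -0.09. At 15 min the cell wall list had a median of -0.02 and a mean of 0.12, sulfur and methionine 0.14 and -0.02, and the respiratory chain -0.20 and 0.00403. Smaller differences in sign occurred for phosphate starvation and core histones at 15 and for phosphate starvation and nitrogen catabolite genes at 60 min. At 30 min they occurred for lipid synthesis, mitochondrial ribosomal proteins, the chaperonin, mating type, multidrug transporters, core histones, meiosis and beta-oxidation.

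The median of all tested genes was -0.05 at 15 min, -0.08 at 30 min and -0.06 at 60 min, and 60 min replicate 2 alone had an array median beyond 0.1 from 0, at -0.18. Setting all arrays to 1 median absolute deviation gave 274 genes higher and 245 lower at 60 min. Without replicate 1, 2 or 3 the count of higher genes at 60 min was 288, 228 and 448, and that of lower genes 265, 321 and 361, and 39 of the 45 named genes passed without any 1 array. The others were RPA43 (-0.78, adjusted p = 0.125), RPC53 (-0.88, 0.0738), GPH1 (0.80, 0.0844) and UGP1 (0.52, 0.267) without replicate 1, and RPC53 (-0.98, 0.0514), CTR1 (0.89, 0.107) and HHF1 (-0.92, 0.0824) without replicate 2. The calls of RNA polymerase I and III (median -0.65, adjusted p = 0.0620) and of trehalose and glycogen (0.52, 0.239) ended without replicate 1, and that of the core histones (-0.80, 0.0972) without replicate 3.

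**Figure D3:**
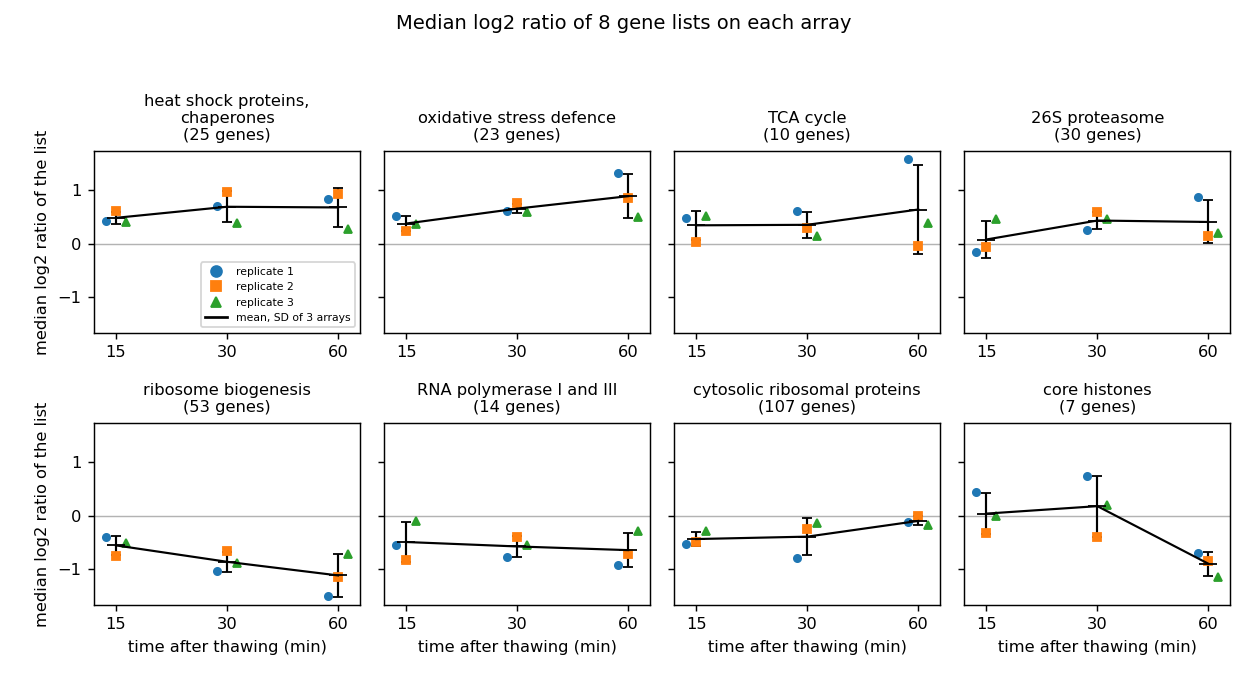
Median log2 ratio (vertical axis) of 8 gene lists on each array at 15, 30 and 60 min after thawing (horizontal axis, times evenly spaced), over members with values on all 9 arrays. Points are arrays and lines with bars are the mean and SD of 3 arrays: the ribosome biogenesis list (53 genes) has a mean of -0.55 at 15 min and -1.11 at 60 min.

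To show which responses lasted, genes called at more than 1 time were counted. Of 1657 genes tested at all 3 times, 13 were higher at each, where 0.0673 would be expected of independent lists. They were ARO9, ATG19, BTN2, HSP104, HSP12, LSP1, MSC1, PGM2, RTC3, SIT1, SPI1, SSA1 and SSA4. Of these, LSP1 and SSA1 were chosen after their values were seen: LSP1, an eisosome component of the plasma membrane, was at 1.43, 1.24 and 2.21 at 15, 30 and 60 min, and SSA1, a cytosolic Hsp70, at 1.32, 1.32 and 1.94. RTC3 was at 3.59, 1.74 and -0.52 on the 3 arrays at 60 min. In limma its call at 15 min ended without replicate 1, 2 or 3 (adjusted p = 0.0590, 0.307 and 0.133). The 3 genes lower at each, where 0.0281 would be expected, were ARO5, DED1 and YHB1. At both 15 and 30 min 14 genes were higher (0.421 expected) and 4 lower (0.196 expected), and at both 30 and 60 min 56 were higher (9.603 expected) and 53 lower (10.3 expected). At both 15 and 60 min 15 were higher (2.75 expected) and 4 lower (1.08 expected). No gene was called in opposite directions at any pair of times. The expected numbers do not allow for shared control cultures or the single dye orientation, which would also bring agreement between times. The 3 tests of a gene also shared 1 estimate of its spread, which the expected numbers leave out as well. Without 1 array the number called at all 3 times lay between 4 (without replicate 3 at 15 min) and 17 (without replicate 2 at 60 min), and it was 5 on the second platform alone.

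Time points were then compared with each other, to show what changed during recovery. Each time point had 1 array on the first and 2 on the second platform, so the platforms were balanced over the times. Between 15 and 30 min, the ribosome biogenesis list was lower at 30 min (58 genes, median difference -0.33, adjusted p = 1.74e-05, and adjusted p = 0.917 with an estimated correlation) and the 26S proteasome list higher (30 genes, 0.33, adjusted p = 0.00863, and adjusted p = 0.917 with an estimated correlation). Neither had a gene that passed, over all genes or adjusted over the list alone. Of 1853 genes tested in limma 0 were higher and 0 lower, and 52 had an unadjusted p under 0.05. The smallest unadjusted p, none of which passed (adjusted p = 0.972 for each, n = 3 per time), belonged to PSA1 (1.22 ± 0.41), APE3 (1.17 ± 0.41), HSP26 (1.28 ± 0.45), RPS2 (1.07 ± 0.39) and RPN10 (1.12 ± 0.40) above 0. Below 0 they belonged to MTR4 (-1.20 ± 0.40), ADE6 (-1.19 ± 0.44), TIF11 (-1.04 ± 0.39), LSM2 (-1.29 ± 0.50) and ADR1 (-1.004 ± 0.40). PSA1 lay at the value shared by ribosomal protein and glycolysis genes on replicate 3 at 30 min, and ADE6 on replicate 1 at 15 min. The call of the 26S proteasome list ended without replicate 1 (0.18, adjusted p = 0.209) or 2 (0.29, 0.0545) at 15 min or replicate 3 at 30 min (0.33, 0.0803), and on the second platform alone (0.29, 0.135). The other 32 lists were not called, with 0 of 582 memberships passed in limma and 16 at an unadjusted p under 0.05.

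Between 30 and 60 min, 1 of 2457 genes passed in limma, and 268 had an unadjusted p under 0.05. OLE1 (YGL055W), the fatty acid desaturase, was 6.33-fold lower at 60 than at 30 min (-2.66 ± 0.52, n = 3 per time, adjusted p = 0.0437). Its 30 min values were 2.48, -0.41 and -0.04 and its 60 min values -2.41, -1.49 and -2.06, and without replicate 1 at 30 min the difference was -1.76 (adjusted p = 0.957). OLE1 did not pass on the second platform alone (-1.54, adjusted p = 0.876) or after centring (-2.63, 0.224) or scaling (-2.30, 0.480) of the arrays. At the same difference of -2.66 it did not pass with a platform block (0.139), a spread from the 2 times alone (0.132), robust moderation (0.0756) or values on at least 2 of 3 arrays (0.0718). It passed with array weights (-2.31, 0.0360) and a replicate block (-2.66, 0.000128). The core histones were lower at 60 min (7 genes, median difference -0.99, adjusted p = 0.00802, and adjusted p = 0.698 with an estimated correlation), with 0 passed over all genes in limma and 5 lower adjusted over the list alone. HHF1, HHF2, HHT1 and HTB1 lay at the shared value on replicate 3 at 30 min. Cytosolic ribosomal proteins were higher (107 genes, 0.26, adjusted p = 0.00303, and adjusted p = 0.698 with an estimated correlation), with 0 passed over all genes and 2 adjusted over the list alone. On the second platform alone that list's difference was 0.10 (adjusted p = 0.0818), and without the genes that have an A and a B copy 0.20 (adjusted p = 0.197). Ribosome biogenesis was lower (70 genes, -0.26, adjusted p = 0.0221, and adjusted p = 0.740 with an estimated correlation), with 0 passed over all genes in limma and 0 adjusted over the list alone, and its call ended without replicate 2 at 30 min (-0.15, adjusted p = 0.267) or replicate 1 at 60 min (-0.0733, adjusted p = 0.821). The respiratory chain was higher (23 genes, 0.31, adjusted p = 0.0263, and adjusted p = 0.698 with an estimated correlation), also with 0 and 0, and its call ended without replicate 2 (0.33, adjusted p = 0.0974) or 3 (0.20, 0.143) at 30 min or replicate 1 at 60 min (0.17, 0.398).

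Other genes with the smallest unadjusted p between 30 and 60 min did not pass in the main fit, which has no replicate block. With that block 18 genes were higher and 15 lower at 60 than at 30 min. Above 0 they included RPS15 (1.90 ± 0.45), HSP26 (1.78 ± 0.45), RPS0B (1.84 ± 0.47) and SAG1 (1.67 ± 0.43), with adjusted p from 0.140 to 0.173. Below 0 they were IZH4 (-2.0003 ± 0.43), EIS1 (-1.95 ± 0.47), ARO5 (-1.62 ± 0.40), CIT2 (-1.76 ± 0.46) and LRP1 (-1.74 ± 0.47), with adjusted p from 0.0738 to 0.201. Of 31 lists not called, fatty acid, sphingolipid and phospholipid synthesis held OLE1 and the other 30 had 0 of 546 memberships passed in limma and 78 at an unadjusted p under 0.05.

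Between 15 and 60 min, 45 genes were higher and 63 lower at 60 min, of 1871 tested in limma, and 460 had an unadjusted p under 0.05. HSP26 was 8.33-fold higher (3.06 ± 0.45, n = 3 per time, adjusted p = 0.000201) and YGP1 6.24-fold (2.64 ± 0.42, adjusted p = 0.000690). RPS15 (2.23 ± 0.45) and HSP12 (2.12 ± 0.48) were also among the largest rises. IZH4 was 8.32-fold lower (-3.06 ± 0.43, adjusted p = 0.000136), CIT2 (YCR005C), the peroxisomal citrate synthase, 5.51-fold lower (-2.46 ± 0.46, adjusted p = 0.00418) and LRP1 4.99-fold lower (-2.32 ± 0.47, adjusted p = 0.00633). DIA1 (-2.29 ± 0.46) and OLE1 (-2.26 ± 0.52) were next, and OLE1 lay at the shared value on replicates 1 and 3 at 15 min. HSP12 did not pass without replicate 1 at 15 min (1.85, adjusted p = 0.0700) or at 60 min (1.94, adjusted p = 0.0509), nor OLE1 without the same arrays (-2.17, adjusted p = 0.0561, and -2.05, adjusted p = 0.0565).

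As lists, ribosome biogenesis (61 genes, median difference -0.51, adjusted p = 9.10e-05, and adjusted p = 0.911 with an estimated correlation) had 6 genes lower at 60 than at 15 min, 10 adjusted over the list alone. Gluconeogenesis, glyoxylate and acetate use (6 genes, -0.88, adjusted p = 0.0162, and adjusted p = 0.911 with an estimated correlation) had 2 lower, also adjusted over the list alone. Core histones (8 genes, -0.71, adjusted p = 0.0162, and adjusted p = 0.911 with an estimated correlation) had 2 lower, 3 adjusted over the list alone, and HHF1, HHT1 and HHT2 lay at the shared value on replicate 3 at 15 min. Oxidative stress defence was higher (25 genes, 0.68, adjusted p = 0.0162, and adjusted p = 0.911 with an estimated correlation), with 1 gene higher over all genes and 6 higher and 1 lower adjusted over the list alone. Cytosolic ribosomal proteins were not called (115 genes, 0.19, adjusted p = 0.187), with 5 genes higher, 2 adjusted over the list alone. Heat shock proteins and chaperones were not called (27 genes, 0.11, adjusted p = 0.619), with 5 genes higher and 3 lower. Without 1 array the count of higher genes lay between 10 (without replicate 1 at 15 min) and 76 (without replicate 3 at 60 min) and that of lower genes between 19 (without replicate 2 at 15 min) and 46 (without replicate 3 at 60 min). Ribosome biogenesis was not called without replicate 1 at 60 min (-0.31, adjusted p = 0.243), nor oxidative stress without that array (0.27, 0.243) or replicate 1 at 15 min (0.74, 0.0853). Gluconeogenesis was not called without replicate 2 at 15 min (-0.94, 0.0549) or replicate 3 at 60 min (-0.48, 0.0543), nor were core histones without replicate 1 at 15 min (-0.60, 0.0922) or replicate 3 at 60 min (-0.65, 0.0707). Setting all arrays to 1 median absolute deviation left 2 genes higher and 2 lower.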

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

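Most results listed here differ between time points. The test of a fixed dye bias was chosen only after the result was seen, and the other tests in this part were chosen before.

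Between 15 and 60 min, 45 genes were higher and 63 lower at 60 min by a test of the difference itself, and 2 and 2 after all arrays were set to 1 median absolute deviation. The largest differences included those of HSP26 (3.06), YGP1 (2.64), RPS15 (2.23) and HSP12 (2.12) above 0, and IZH4 (-3.06), CIT2 (-2.46), LRP1 (-2.32), DIA1 (-2.29) and OLE1 (-2.26) below 0. Also past the test, and chosen after their values were seen because their arrays at 15 and 60 min lie on opposite sides of 0, were RPS0B (1.81), ADR1 (-1.65) and EIS1 (-1.96). EIS1 lay at the value shared by ribosomal protein and glycolysis genes on replicate 1 at 15 min. It was among 38 of 2463 genes outside those lists that did so there. Lists that differed were ribosome biogenesis (-0.51), gluconeogenesis, glyoxylate and acetate use (-0.88), oxidative stress defence (0.68) and core histones (-0.71), each lost with an estimated correlation (adjusted p = 0.911 for each). The lists of mitochondrial ribosomal proteins (0.30) and nitrogen catabolite genes (-0.33) had array medians, over members with values on all 9 arrays, on opposite sides of 0 at 15 and 60 min and did not pass (adjusted p = 0.417 for each).

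Between 30 and 60 min, 1 gene was lower, OLE1 (-2.66), and its call ended without replicate 1 (adjusted p = 0.957) or 2 (0.178) at 30 min and without replicate 1 (0.113) or 3 (0.0719) at 60 min. Lists that differed were cytosolic ribosomal proteins (0.26), core histones (-0.99), ribosome biogenesis (-0.26) and the respiratory chain (0.31), each lost with an estimated correlation (adjusted p from 0.698 to 0.740). EIS1 (-1.95, adjusted p = 0.140) and CIT2 (-1.76, adjusted p = 0.173) lay on opposite sides of 0 at 30 and 60 min and did not pass. Nor did the gluconeogenesis list (-0.51, adjusted p = 0.216), whose array medians over the 6 members with values on all 9 arrays lay on opposite sides of 0, while its medians over all tested members were 0.34 and 0.19. Between 15 and 30 min, the lists of ribosome biogenesis (-0.33) and the 26S proteasome (0.33) differed, each lost with an estimated correlation (adjusted p = 0.917 for each). PSA1 (1.22), RPS2 (1.07) and ADR1 (-1.004) lay on opposite sides of 0 on all arrays of the 2 times and did not pass (adjusted p = 0.972 for each).

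The 961 spots without a gene symbol were used only where every spot was tested on its own. Of these spots 75 were tested at 15 min, 240 at 30 min and 136 at 60 min. Among those tested, limma called 1 at 15 min, 8 at 30 min and 29 at 60 min.

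The first pattern weighed is that the array medians of the ribosomal protein list were nearer to 0 at 60 than at 15 min while the mean of those of ribosome biogenesis was further below 0. By the test of lists the former was not called between these times (0.19, adjusted p = 0.187). The call of the latter ended without replicate 1 at 60 min (adjusted p = 0.243), and its array medians at the 2 times overlapped. A bias of the dyes that is the same on every array would cancel in a difference between times, so it could not by itself give this pattern. Whether the pattern exceeds the variation between arrays stays open. The ribosomal protein list's array medians were -0.53, -0.49 and -0.28 at 15 min and -0.12, -0.0048 and -0.17 at 60 min, a difference of 2.99 pooled SD with no overlap, but this restates the pattern, and 3 against 3 arrays lie apart in 10% of cases by chance. Cross-hybridisation between copies of ribosomal protein genes is not settled. The 27 genes without an A or B partner on the arrays shifted 1.06 times as much as genes with one (0.31 and 0.29). Some of the 27 may have a copy that was missing from the arrays, so they cannot decide it. A pull of the LOWESS correction on abundant transcripts stays open as well: the gap to the glycolysis list changed by 0.462 pooled SD, but that SD (0.521) exceeds the 0.34 to be explained, and a change in the cells over time stays open, untested.

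The second pattern is that 979 genes were called at 60 min and 25 at 15 min. A wider ratio scale of the 60 min arrays as the whole cause is argued against by the counts after all arrays were set to 1 median absolute deviation, 519 and 62, a ratio of 8.37. The same scaling took the test between 15 and 60 min from 45 and 63 genes to 2 and 2, so a wider scale as part of the cause stays open. Fewer tested genes at 15 min are argued against by the 1871 genes tested at both times, of which 640 were called at 60 min and 23 at 15 min, a ratio of 27.8. The median gene SD was no larger at 15 min (0.474) than at 60 min (0.485, ratio 0.977). Set against the median absolute log2 ratio, 0.30 at 15 min and 0.54 at 60 min, the spread at 15 min was the larger. The fit gave each gene 1 spread for all times, so the SD at 15 min did not by itself set the calls there. With a spread from each time point alone, 38 genes were higher and 10 lower at 15 min, and 338 and 372 at 60 min. A stronger response of the cells at 60 min is a hypothesis that stays open, as do differences between the arrays that were not tested.

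The real orientation of the arrays was the only 1 of 4 ways of exchanging channels to give as many calls at 15 min (25, highest other 0), at 30 min (144, highest other 0) and at 60 min (979, highest other 0), and 4 are too few for a share under 0.05. Of the 10 splits of 6 arrays into 3 and 3, all 10 gave as many genes as the real one between 15 and 30 min (0, highest other 0), 1 between 30 and 60 min (1, highest other 0) and 1 between 15 and 60 min (108, highest other 22). Such splits are also too few for a share under 0.05.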

How the results depend on the processing

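The platform block, the second platform alone and the setting of shared values to missing were chosen after seeing the data, and the cause of the changes given here was not tested except that leaving out arrays leaves fewer arrays. Leaving out 1 array gave 5 to 11 genes higher (18 with all arrays) and 0 to 3 lower (7) at 15 min, 11 to 58 higher (76) and 3 to 26 lower (68) at 30 min, and 228 to 448 higher (461) and 265 to 361 lower (518) at 60 min. It gave 0 higher and 0 lower in limma between 15 and 30 min, 0 to 2 higher (0) and 0 to 3 lower (1) between 30 and 60 min, and 10 to 76 higher (45) and 19 to 46 lower (63) between 15 and 60 min. For lists it gave 7 to 10 higher (8) and 3 to 6 lower (4) at 15 min, 9 to 10 higher (11) and 3 to 6 lower (5) at 30 min, and 5 to 11 higher (6) and 2 to 5 lower (3) at 60 min. Lists that differed numbered 1 to 4 (2) between 15 and 30 min, 2 to 9 (4) between 30 and 60 min and 2 to 6 (4) between 15 and 60 min, and genes called at all 3 times 4 to 17 (16). The median of the ribosome biogenesis list between 30 and 60 min, -0.26, lay between -0.43 and -0.0733, and without replicate 1 at 60 min its test was reversed (median -0.0733, adjusted p = 0.821).

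Centring each array on its median gave 2 genes lower at 15 min, 42 lower at 30 min, 0 lower between 30 and 60 min, 25 higher and 33 lower between 15 and 60 min, and 10 at all 3 times. Setting arrays to 1 median absolute deviation gave 44 higher and 18 lower at 15 min, 159 and 169 at 30 min, 274 and 245 at 60 min, 0 lower between 30 and 60 min, and 2 and 2 between 15 and 60 min. A spread from the time points compared alone gave 38 higher at 15 min, 159 higher and 154 lower at 30 min, 0 lower between 30 and 60 min and 27 higher between 15 and 60 min. Array weights gave 244 higher and 412 lower at 30 min, 2 lower between 30 and 60 min, and 23 higher and 40 lower between 15 and 60 min. Values on at least 2 of 3 arrays, robust moderation and testing every spot each gave 0 lower between 30 and 60 min, where 268 genes had an unadjusted p under 0.05 in limma. Leaving out genes with an absolute ratio over 5 gave 11 lower at 15 min, and a minimum change of 1 log2 unit gave 293 higher and 278 lower at 60 min.

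Arrays of equal replicate number correlated at 0.02 to 0.53 after removal of the time means, 7 of 9 pairs above 0.1 and 8 of 9 arrays best with their own number, which did not meet the rule for pairing. With the replicate block 88 genes were higher and 73 lower at 15 min, 184 and 202 at 30 min, 18 and 15 between 30 and 60 min, and 131 and 160 between 15 and 60 min, with 55 at all 3 times. In tests of a time point against 0, this block takes differences between replicate numbers out of the error. Its counts at 15 min, at 30 min and at all 3 times thus leave out that spread and may be too high. With a platform block 2 were lower at 15 min, 0 lower between 30 and 60 min, and 10 called at all 3 times. The second platform alone gave 0 lower at 15 min, 29 higher and 5 lower at 30 min, 278 and 266 at 60 min, 0 lower between 30 and 60 min, 2 and 6 between 15 and 60 min, and 5 at all 3 times, with 3 lists lower at 30 min and 1 list differing between 15 and 60 min. With the shared values set to missing 11 genes were lower at 15 min.

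With an estimated correlation 0 lists were called at any time or between any times by limma. By fry 0 lists were higher and 0 lower at 15 min, 5 higher and 5 lower at 30 min, 6 higher and 6 lower at 60 min, and 0 differed between 15 and 30, 30 and 60 or 15 and 60 min. Of 2243 values of the 144 results for named genes under alternatives, 1996 kept direction and side of the threshold, 233 no longer passed, 14 newly passed and 0 reversed. Of 546 for 47 list results, 414 kept both, 131 no longer passed and 1 reversed. A filter on dim or marked spots was not run because the tables used here hold no intensities, and signal over background is unknown. One fit of all 9 arrays is the fit reported.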

Other observations

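Genes in this paragraph were chosen after their values were seen. At 60 min the proteasome genes that passed were higher except RPN4 and RPN5: PRE6 was at 2.36 ± 0.34, PUP2 at 1.503 and PRE2 at 1.40, and RPN4, the transcription factor of proteasome genes, was at -1.10 ± 0.29 (adjusted p = 0.00595, lower on 3 of 3 arrays). RPN4 was at 0.75 at 15 min (adjusted p = 0.192), and its difference between 15 and 60 min was -1.85 (adjusted p = 0.013). The cytochrome c oxidase isoform COX5B was at 2.65 ± 0.31 at 60 min and COX5A at -0.05 ± 0.30 (adjusted p = 0.908). At 60 min HEM13 was at -2.20 ± 0.32 and OLE1 at -1.99 ± 0.37. Among regulators of stress genes, MSN4 (-0.98 ± 0.32) and YAP1 (-0.78 ± 0.28) were lower and HSF1 (0.87 ± 0.29) higher at 60 min. The co-chaperone YDJ1 (-1.03 ± 0.30) and the mitochondrial Hsp70 SSC1 (-0.97 ± 0.30) were lower, and SSA1 (1.94 ± 0.33) and HSP60 (1.65) higher.

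Also chosen after their values were seen, translation factors lower at 60 min included NIP1 (-1.68 ± 0.28) and TIF3 (-1.42 ± 0.29), subunits or partners of the initiation machinery. Actin patch genes higher at 60 min included ARP3 (1.64 ± 0.30), SAC6 (1.54 ± 0.32) and ARC19 (1.499 ± 0.31). The alpha-agglutinin gene SAG1 was at 2.43 ± 0.31 and AFB1, which blocks a-factor, at 2.02 ± 0.31, while MF(ALPHA)2 was at -0.79. ARO10, which had values on 6 of the 9 arrays and was not tested, lay between 2.09 and 4.50.

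The third pattern weighed is the value that ribosomal protein and glycolysis genes shared within 0.01 log2 units on 5 of 9 arrays. Both tests of it were chosen only after the result was seen. The fullest window held 11, 26, 26, 17 and 15 genes on those arrays, and the highest of 1000 draws from smoothed values held 9, 15, 14, 10 and 11. Regulation of these genes as 1 group is argued against by their spread on the other arrays of the time point, where their SD was 0.784 of that of the other genes of both lists. Signal saturation in both channels may account for it: the same genes recurred at the shared value 2.84 times as often between arrays as independent draws would give, and no intensities were at hand to test it further.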
